A study of Rattus norvegicus and Mus musculus with 17 samples.

How the data were processed

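The aligner, the genome build, the annotation and the counting of reads were not given in the sources used here. The samples were 17 RNA sequencing libraries of male animals: DEN-treated C57BL/6 mouse liver before tumours (n = 3) and with tumours (n = 3), and ACI rat control liver (n = 3), Morris hepatoma (n = 4) and regenerating liver (n = 4). The labels name no sequencing batch and do not pair the libraries.

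The authors deposited 3 tables, each with RPKM values per library, in which 0.001 stands for no reads. The deposited headers name no unit. The values were read as RPKM, since low values of a gene moved in steps that shared 1 depth per library. In the DEN table the steps and the transcript length gave the most common implied depth, within 0.5 M reads, in 169 of 729 genes, and this was not tested in the rat tables. Per the file headers the tables also give the log2 ratio of the group means of RPKM, and this equalled the recomputed ratio within 0.01 in all 4649, 9082 and 2093 listed genes. The deposited p-value equalled an unadjusted two-sided comparison of the group means of linear RPKM with equal variances within 1% in all of these genes, although its header names a Holm correction, and no listed gene had a deposited p-value of 0.05 or more. With a Holm correction over the listed genes, 14, 72 and 5 genes would pass. The tables listed 1328 genes higher and 3321 lower for DEN, 7973 and 1109 for Morris hepatoma, and 1965 and 128 for regenerating liver. Of the listed genes 4360, 9051 and 2091 matched the reference annotation. A line without a gene was left out of the Morris table.

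RPKM values were tested as log2(RPKM + 1) with limma 3.58.1 (trend and robust settings, two-sided) in R 4.3.3, keeping genes with at least 1 RPKM in as many libraries as the smaller group. Calls had a Benjamini-Hochberg adjusted p under 0.05. Because the tables hold only genes that had already passed a p-value of 0.05, the adjustment counted all protein-coding genes of the annotation, 21951 in mouse (GENCODE M21) and 23154 in rat (RefSeq GRCr8). This number was set after the tables were seen to be preselected, in place of the number of tested genes planned before. The procedure was tested on simulated data passed through the same selection. With no gene changed, adjustment over the listed genes called 791, 671 and 758 genes falsely in DEN, Morris and regenerating designs, and adjustment over all annotated genes 0, 0 and 1. With 200 genes changed it called 181, 155 and 195 genes, of which 18, 16 and 21 falsely, and found 69%, 50% and 76% of 2-fold and 94%, 89% and 98% of 4-fold changes. In each design a larger share of these calls was false than the threshold of 0.05 allows, so adjusted p-values may be too small. In the simulated direct comparison it found 79% of 4-fold differences and called 0 of 100 equal genes. Simulated genes took their mean and spread from listed genes, which had been selected for a difference large against their spread. They were drawn independently, without shifts shared within a library, and the changed ones were drawn from better expressed genes. The shares found and falsely called may therefore differ in the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

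Transcript lengths were those of the longest mouse transcript of the same symbol, for the rat tables too. Library depth was read from the steps of low values, and in rats only relative to control library 1, so no counting intervals are given. The comparisons were DEN liver with against before tumours, Morris hepatoma against control, regenerating liver against control, and Morris hepatoma against regenerating liver on genes listed in both rat tables. Overlaps were counted over genes tested in both comparisons, with n1 × n2 / N as the number for independent lists and a two-sided Fisher exact test between species, where genes were matched by identical symbol without regard to case. Overlap of the rat comparisons was set against 20 simulated draws of unchanged groups that share the controls.

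Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were mitosis, DNA replication and G1/S, plasma proteins, hepatocyte transcription factors, xenobiotic (drug) metabolism, bile acid synthesis and transport, urea cycle and amino acid catabolism, gluconeogenesis and glycogen, fatty acid oxidation, lipogenesis, cholesterol biosynthesis, oncofetal and liver tumour markers, glycolysis, beta-catenin and perivenous genes, matrix and stellate cells, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, endothelial cells, cholangiocytes, erythroid cells, acute phase response, interferon response, p53 targets, NRF2 targets, growth hormone and IGF axis, immediate early genes, ribosome biogenesis and hypoxia. Some genes are members of several of these lists, so their counts are not separate. Among them are Mcm2 (DNA replication and tumour markers), Btg2 (p53 targets and immediate early genes), and Cyp1a2 and Cyp2e1 (drug metabolism and perivenous genes). Lists of male-biased and female-biased mouse liver genes were written later. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. As the tables hold only selected genes, camera compared a list with other listed genes, not with the whole transcriptome.

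Named genes were (a) the 6 largest rises and 6 largest falls per comparison among genes past the threshold with groups that do not overlap, a mean above the median and no predicted-gene symbol, (b) up to 3 members with the smallest p per described list, (c) Mki67, Ccnd1, Cdkn1a, Myc, Alb, Hnf4a, Cyp7a1, Glul, Afp, Gpc3, H19 and Igf2 in every comparison, and (d) the 6 genes with the strongest evidence among those called the same way in all 3 comparisons, and among those called alike in both tumour models and opposite in regenerating liver. Some genes taken by this rule are not reported here, and no others took their place. Members that moved against their list, members of counts of 5 or fewer, and Ttr, Cyp2e1, Clec4f and Cd5l were chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, median scaling and quantile normalization, adjusted p under 0.01, at least a 2-fold change, each library left out in turn, the replicate number as a block, and all 3 rat groups in 1 fit. Adjustment over the listed genes alone, the deposited p-values, and pairs of hepatoma libraries left out were added after seeing the data. The pairs followed the level of hepatocyte transcripts in the hepatoma libraries. Median scaling and quantile normalization used the tested genes alone, all preselected as changed. They take out any shift these genes share, real or not. Alternatives planned for count tables were not run, because the values analysed here are RPKM.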

Results

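Liver gene expression was measured by RNA sequencing in 17 libraries from male animals, covering 2 models of liver cancer and regenerating liver. C57BL/6 mice received the liver carcinogen diethylnitrosamine (DEN) at 50 mg/kg at 14 days of age and TCPOBOP, a ligand of the nuclear receptor CAR, at 2 mg/kg 30 days later. Their livers were taken at 5 months, before tumours (n = 3), or at 8 months, with tumours (n = 3). ACI rats of 10 weeks received MH3924a cells, a transplantable Morris hepatoma line, in the liver, and the tumours were taken 2 weeks later (n = 4). Regenerating rat liver was taken 24 hours after partial hepatectomy (n = 4), and untreated ACI liver served as control for both rat groups (n = 3). The labels do not say that each library came from an animal of its own, so the p-values measure the spread between these libraries.

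The 3 deposited tables hold values read as RPKM and list only genes with a deposited p-value under 0.05. They hold 4649 genes for the DEN model, 9082 for the Morris hepatoma and 2093 for regenerating liver, and a gene that is not listed has no value here. The depths implied by the steps of low values and transcript length, from the most common estimate within 0.5 M (169 of 729 genes), were 33.5, 34.2 and 31.6 M reads for DEN libraries 1 to 3 before tumours, and 37.5, 34.8 and 40.7 for libraries 1 to 3 with tumours. Rat depths were known only relative to control library 1. They were 1.02 and 1.14 for control libraries 2 and 3, 1.06, 1.08, 1.02 and 1.02 for hepatoma libraries 1 to 4, and 1.18, 1.04, 1.07 and 1.09 for regenerating libraries 1 to 4. Values are given as mean ± SD in RPKM, and fold changes as log2 of RPKM + 1 ± SE, a scale that understates changes of low genes.

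The first comparison asked which genes differed between DEN livers with tumours and DEN livers before tumours. Age differed with tumour status (8 and 5 months). Liver with tumours held more transcripts of liver tumour markers, cell division genes, p53 targets and immediate early genes, and fewer of perivenous, drug metabolism, bile acid and amino acid genes. Golm1, a Golgi glycoprotein raised in liver cancer, rose from 1.25 ± 0.607 to 20.02 ± 6.28 RPKM (log2 fold change 3.21 ± 0.27, adjusted p = 0.00048). The p53 target and cell cycle inhibitor Cdkn1a rose from 7.19 ± 1.78 to 37.5 ± 3.35 RPKM (2.25 ± 0.17, adjusted p = 0.00029). Glul, the glutamine synthetase of perivenous hepatocytes, fell from 251 ± 16.3 to 31.5 ± 19.1 RPKM (-3.20 ± 0.52, adjusted p = 0.0095).

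Of 3684 genes tested in the DEN model, 658 rose, 1823 fell and 1203 did not pass the threshold. At least a 2-fold change was seen in 1055 of the genes that passed. The median log2 fold change of the tested genes was -0.56, and setting library medians equal changed the split to 912 higher and 614 lower, and quantile normalization to 883 and 589. Both scalings rest on genes selected as changed, so they take out any shift these genes share, real or not. List medians are therefore given relative to the median of the tested genes.

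The largest rises were in Akr1c18, a steroid dehydrogenase (GeneID 105349, 5.51 ± 7.62 to 262 ± 124 RPKM), Cyp2a4, a steroid hydroxylase (13086, 18.1, 246 and 36.1 in libraries 1 to 3 before tumours, to 2919 ± 1528), the protease inhibitor gene Spink3 (20730, 0.285 ± 0.277 to 66.4 ± 40.7), the lectin receptor gene Klrb1b (80782, 1.23 ± 1.64 to 54.7 ± 17.2), the tetraspanin gene Tspan8 (216350, 2.96 ± 4.07 to 69.2 ± 18.3) and the oncofetal glypican Gpc3 (14734, 5.13 ± 7.70 to 83.8 ± 31.4). Their log2 fold changes ran from 5.87 ± 0.85 for Akr1c18 to 4.54 ± 0.86 for Gpc3. The largest falls were in the major urinary protein genes Mup17 (100039206, 6908 ± 2523 to 94.1 ± 103 RPKM, log2 fold change -6.70 ± 0.78) and Mup16 (100039177, 328 ± 108 to 5.31 ± 3.51, -5.78 ± 0.42). The cytochrome P450 genes Cyp2c54 (404195, 1203 ± 409 to 24.96 ± 35.8 RPKM), Cyp2c55 (72082, 356 ± 134 to 3.86 ± 4.92), Cyp2c50 (107141, 2338 ± 690 to 72.7 ± 103) and Cyp2c37 (13096, 950 ± 416 to 30.2 ± 41.4) fell with them. The Mup and Cyp2c families hold near-identical copies whose reads the authors' counting could have split, so single members are uncertain. Library 2 before tumours had 14.3 RPKM of Akr1c18 and 14.0 of Gpc3, against 0.701 and 1.54 of Akr1c18 and 0.578 and 0.780 of Gpc3 in libraries 1 and 3.

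Cell division genes were higher in the DEN livers with tumours. All 13 tested mitosis genes rose (13 adjusted over the list alone), among them Ccnb2 (0.792 ± 0.0514 to 4.85 ± 1.40 RPKM, adjusted p = 0.00096), Ccna2 (1.41 ± 0.21 on the log2 scale) and Aurkb (1.25 ± 0.19). Mki67 rose from 0.475 ± 0.0601 to 3.08 ± 1.35 RPKM. The median of the mitosis list lay 1.80 above that of the tested genes (camera adjusted p = 1.4e-08). With an estimated correlation this call was lost (adjusted p = 0.45), as was each of the 14 list calls among 22 lists in this comparison (0.43 to 0.59). DNA replication and G1/S genes went both ways, with 5 of 11 higher, 2 lower and 4 not past the threshold (6 higher and 3 lower adjusted over the list alone, relative median 1.14, adjusted p = 0.0069). Ccne1, the cyclin of S phase entry, rose by 1.92 ± 0.26 on the log2 scale, and Ccnd1 by 1.13 ± 0.21, whereas Mcm10 changed by -1.77 ± 0.18 and Tk1 by -1.17 ± 0.15. Under median scaling 8 of this list were higher and 2 lower, and under quantile normalization 7 and 1. Of the p53 targets 8 of 9 rose and Fas fell (8 and 1 adjusted over the list alone, relative median 1.60, adjusted p = 2.1e-05). Cdkn1a, Btg2 (2.46 ± 0.19) and Psrc1 (2.14 ± 0.22) led them, and Btg2 is also a member of the immediate early list. All 9 tested immediate early genes rose (9 adjusted over the list alone, relative median 1.78, adjusted p = 4e-07), among them Egr1 (4.05 ± 0.752 to 51.6 ± 10.9 RPKM), Ier3 (2.00 ± 0.15 on the log2 scale) and Myc (0.67 ± 0.15).

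Of the liver tumour markers 9 of 10 rose (9 adjusted over the list alone, relative median 4.44, adjusted p = 1.4e-06), with Scd2 at 3.65 ± 0.38 and Spink3 at 5.56 ± 0.42 on the log2 scale. The exception was Gstp1, a glutathione transferase, which fell. All 6 tested matrix and stellate cell genes rose (6 adjusted over the list alone, relative median 1.81, adjusted p = 2.7e-05), among them the basement membrane collagens Col4a2 (1.47 ± 0.15) and Col4a1 (1.53 ± 0.19) and the protease inhibitor Timp1 (1.03 ± 0.14). Endothelial genes were mostly higher, with Emcn (1.40 ± 0.23) and Cd34 (1.42 ± 0.27) among 5 of 7 that rose and 1, Tie1, that fell (5 and 2 adjusted over the list alone, relative median 1.30, adjusted p = 0.016, and 0.053 under quantile normalization).

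All 16 tested beta-catenin and perivenous genes fell (16 adjusted over the list alone, relative median -1.65, adjusted p = 0.0016), among them the ammonium transporter Rhbg (9.54 ± 1.88 to 0.720 ± 0.1704 RPKM), the Wnt-responsive transcription factor Tbx3 (7.92 ± 1.98 to 0.418 ± 0.116) and Lect2 (356 ± 82.3 to 60.2 ± 9.39). Under median scaling 13 of the 16 fell and under quantile normalization 16. Of the drug metabolism genes 27 of 29 fell (28 adjusted over the list alone, relative median -1.73, adjusted p = 0.0016), including Cyp2d9 (1806 ± 219 to 182 ± 50.8 RPKM), Gsta3 (-1.80 ± 0.17 on the log2 scale) and Ces2a (-4.52 ± 0.42). Cyp2a4 was the 1 that rose. Under median scaling 24 fell and under quantile normalization 19. All 13 bile acid genes fell (13 adjusted over the list alone, relative median -1.66, adjusted p = 0.0073), including the conjugating enzymes Slc27a5 (-1.85 ± 0.20) and Baat (-1.90 ± 0.22) and the synthesis enzyme Hsd3b7 (-2.05 ± 0.21). Of the urea cycle and amino acid genes 14 of 16 fell (16 adjusted over the list alone, relative median -0.65, adjusted p = 0.017), led by Prodh (-3.32 ± 0.26), Haao (-1.62 ± 0.17) and Asl (-1.58 ± 0.20). Under median scaling 7 fell and under quantile normalization 4. Hepatocyte transcription factors fell in 11 of 12 cases (12 adjusted over the list alone, relative median -0.41, adjusted p = 0.045), among them Tef (-1.56 ± 0.19), Hlf (-1.11 ± 0.15) and the bile acid receptor Nr1h4 (-1.96 ± 0.29). Under median scaling 3 fell and under quantile normalization 4. This list call was lost with filter at 5 (0.15), under quantile normalization (0.053) and without library 1 before tumours (0.051).

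Plasma protein genes split, with 7 of 18 higher and 4 lower (8 and 7 adjusted over the list alone), against 8 and 1 under median scaling and 9 and 1 under quantile normalization. Alb rose from 24700 ± 3706 to 83080 ± 3711 RPKM (1.76 ± 0.17), Ahsg by 1.90 ± 0.17 and Itih2 by 1.42 ± 0.16. The list median was -0.33, which was 0.23 above that of the tested genes (camera direction up, adjusted p = 0.029) and turned to 0.07 and 0.58 under the 2 scalings. This list call was lost without a filter (0.099), under median scaling (0.065) and without library 1 before tumours (0.051) or library 2 with tumours (0.052). Acute phase genes also split, with 5 of 10 higher, among them Apcs (1.67 ± 0.21) and Il1rn (3.03 ± 0.37), and 3 lower, among them Orm2 (-2.33 ± 0.23), with 6 and 4 adjusted over the list alone (relative median 1.40, adjusted p = 0.026). Under each scaling 6 were higher and 1 lower. Their list call was lost without a filter (0.05), under median scaling (0.089) and without library 1 before tumours (0.051). Hnf4a, Cyp7a1, Afp, H19 and Igf2 were not listed.

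**Figure D1:**
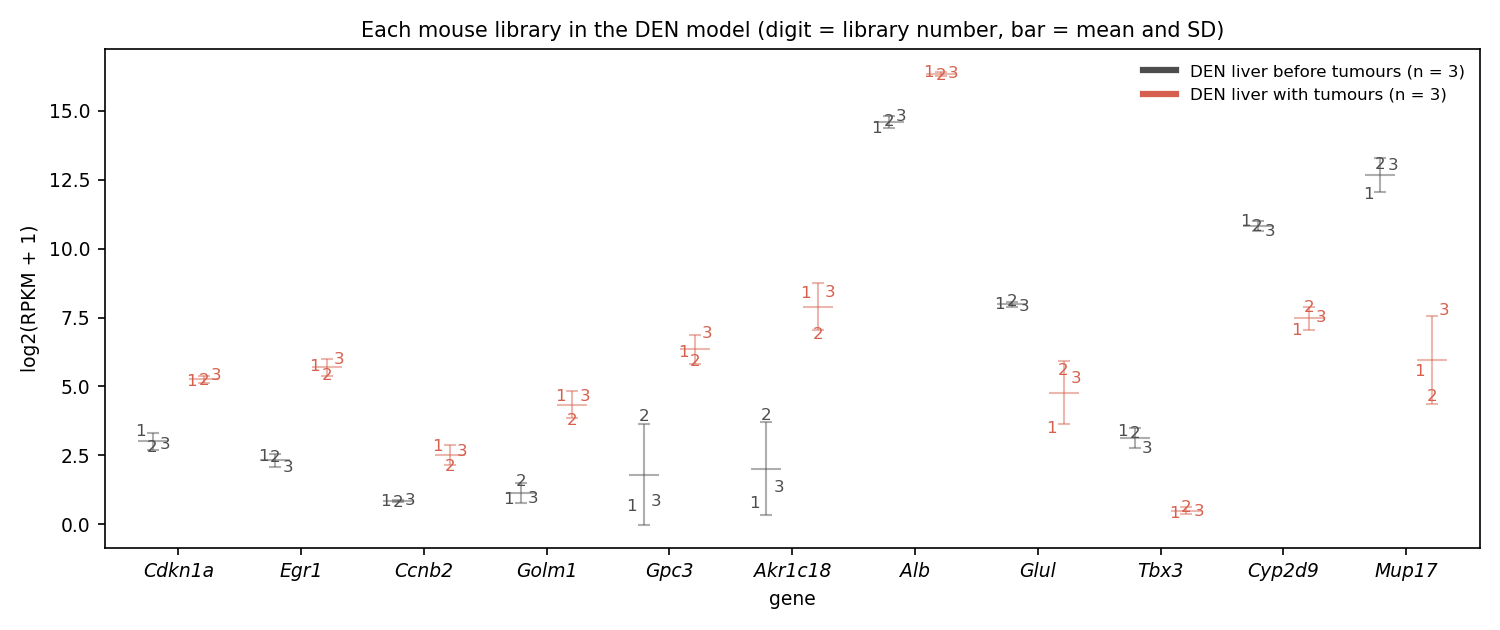
Expression of 11 genes in each DEN library, as log2(RPKM + 1), with grey digits for libraries before tumours (n = 3), red digits for libraries with tumours (n = 3), and bars for the mean and SD of each group. Alb, Cdkn1a, Egr1, Ccnb2 and Golm1 were higher and Glul, Tbx3, Cyp2d9 and Mup17 lower in each of the 3 libraries with tumours, and library 2 before tumours held 14.0 RPKM of Gpc3.

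Of the 99 genes that passed and are named by the rule, 24 lost the call without at least 1 library. Without library 1 before tumours 448 genes rose and 922 fell, without library 2 before tumours 409 and 938, and without library 3 with tumours 444 and 1093. Without library 3 with tumours the calls of Akr1c18 (adjusted p = 0.099), Cyp2a4 (0.13), Tspan8 (0.075) and Cyp2c54 (0.12) were lost. Those of Cyp2c50 and Cyp2c37 (up to 0.16 each) were lost without it or library 1 or 2 before tumours, and that of Myc (up to 0.099) without it or library 2 or 3 before tumours. Ccnd1 lost its call without library 2 or 3 before tumours (up to 0.051), Cd34 without library 3 before tumours (0.054), and Gpc3 without any of 5 of the 6 libraries (up to 0.19).

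The second comparison asked which genes differed between Morris hepatoma and control rat liver. The hepatoma held far more transcripts of cell division, ribosome biogenesis, glycolysis and matrix genes than control liver, and fewer of bile acid and amino acid genes. Akr1b8, an aldo-keto reductase of liver tumours (GeneID 286921), rose from 0.510 ± 0.265 to 759 ± 160 RPKM (log2 fold change 8.97 ± 0.23, adjusted p = 1.3e-07, n = 3 and 4). The glucose transporter Slc2a1 rose from 2.67 ± 0.407 to 200.3 ± 35.3 RPKM (5.77 ± 0.20, adjusted p = 1.8e-07). The sterol transporter Abcg5 fell from 1.84 ± 0.0601 to 0.193 ± 0.151 RPKM (-1.26 ± 0.14, adjusted p = 4.4e-05).

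Of 8233 genes tested, 7042 rose, 719 fell and 472 did not pass the threshold, and 6601 of those that passed changed at least 2-fold. The median log2 fold change of the tested genes was 1.58. Setting library medians equal gave 2030 higher and 2389 lower, and quantile normalization 2514 and 1878, so that the split of directions depends on the scaling. As most listed genes were selected as higher, scaling on them evens out the split by construction and cannot tell which split is right.

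The largest rises after Akr1b8 were in the cell cycle inhibitor locus Cdkn2a (GeneID 25163, 0.190 ± 0.101 to 497 ± 163 RPKM), the annexin Anxa2 (56611, 7.67 ± 5.63 to 2026 ± 409), the urokinase receptor Plaur (50692, 0.916 ± 0.860 to 406 ± 78.7), the pyruvate kinase Pkm (25630, 8.68 ± 7.92 to 1781 ± 531) and the calcium-binding protein gene S100a6 (85247, 2.15 ± 1.74 to 586 ± 309). The largest falls were in Cyp3a2 (266682, 1199 ± 939 to 9.95 ± 6.84 RPKM), the apolipoprotein Apoa2 (25649, 3855 ± 2848 to 48.3 ± 47.4), Rup2 (619560, 8169 ± 4430 to 225 ± 216), the paraoxonase Pon1 (84024, 1285 ± 901 to 29.8 ± 28.5), Cyp2c23 (83790, 1079 ± 661 to 33.8 ± 35.5) and Cyp2c13 (171521, 1040 ± 791 to 19.5 ± 19.04). Log2 fold changes of these 6 ran from -6.54 ± 1.38 to -5.90 ± 1.54.

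All 24 tested mitosis genes rose (24 adjusted over the list alone, relative median 2.29, adjusted p = 0.00074), among them Kif23 (0.210 ± 0.125 to 30.4 ± 5.34 RPKM), Plk1 (4.96 ± 0.23 on the log2 scale) and Tpx2 (4.65 ± 0.22). With an estimated correlation this call was lost (adjusted p = 0.58), as was each of the 15 list calls among 25 lists in this comparison (0.14 to 0.58). Of the DNA replication and G1/S genes 31 of 32 rose, among them Mcm3 (4.94 ± 0.23), Uhrf1 (4.33 ± 0.20), Mcm4 (4.70 ± 0.23) and Ccnd1 (3.70 ± 0.27), and 1 fell (31 and 1 adjusted over the list alone, relative median 1.92, adjusted p = 0.0045). All 23 ribosome biogenesis genes rose (23 adjusted over the list alone, relative median 1.31, adjusted p = 0.009), with Rrp9 (3.81 ± 0.18), Ddx21 (3.48 ± 0.17) and Nop58 (3.32 ± 0.18) in front. Under median scaling 16 rose and under quantile normalization 17. Of the glycolysis genes 18 of 19 rose, among them Slc2a1, Hk2 (4.68 ± 0.21) and Hk1 (4.74 ± 0.22), and Ldha did not pass (19 adjusted over the list alone, relative median 1.42, adjusted p = 0.048). The glycolysis call was lost with pseudocount 0.1 (0.064), filter at 5 (0.061) and the replicate block (0.089), and without control library 2 (0.055) or hepatoma library 1, 2 or 3 (up to 0.079). With all 3 rat groups in 1 fit, which tests fewer genes, the calls of the mitosis (0.22), DNA replication (0.12) and ribosome biogenesis lists (0.22) were lost. Myc rose from 9.09 ± 2.18 to 108 ± 24.6 RPKM.

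Other groups rose member by member, while their lists passed the test against the other listed genes under some alternatives alone. All 20 matrix and stellate cell genes rose (20 adjusted over the list alone, camera adjusted p = 0.12), among them Postn (0.0279 ± 0.0339 to 40.01 ± 12.8 RPKM), Vim (23.1 ± 11.9 to 3680 ± 1208) and Col1a1 (1.65 ± 1.15 to 217 ± 95.4). All 11 hypoxia genes rose (11 adjusted over the list alone, adjusted p = 0.24), led by Ndrg1 (5.89 ± 0.25), P4ha1 (4.37 ± 0.29) and Adm (5.55 ± 0.35). All 14 immediate early genes rose (14 adjusted over the list alone, adjusted p = 0.14), with Fosl1 (0.0261 ± 0.0452 to 49.2 ± 6.77 RPKM) in front. Of the liver tumour markers 11 of 13 rose, among them the RNA-binding protein genes Igf2bp1 (5.30 ± 0.18) and Igf2bp2 (4.15 ± 0.19), and Afp went from 6.20 ± 0.302 to 0.943 ± 1.07 RPKM (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.60). Under median scaling 11 matrix, 6 hypoxia, 9 immediate early and 7 tumour marker genes were higher, and these 4 lists passed (4.7e-05, 0.028, 0.00058 and 0.015). The matrix list also passed without control library 3 (0.022).

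Hepatocyte genes were lower in the hepatoma, by amounts that differed between its libraries. Alb, the gene of albumin, was at 574, 19, 10940 and 10920 RPKM in hepatoma libraries 1 to 4, against 67210, 60250 and 48190 in control libraries 1 to 3 (log2 fold change -5.74 ± 2.44, adjusted p = 0.17). Clec4f, a receptor of Kupffer cells, was at 6.39, 6.02, 26.8 and 24.96 RPKM in hepatoma libraries 1 to 4, against 79.0, 91.9 and 70.2 in the controls. Control library 3 also stood apart, with 4688 RPKM of Ttr against 20080 and 17380 in control libraries 1 and 2, and 451 of Cyp2e1 against 3045 and 3687.

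Plasma protein genes had the lowest relative median of the lists, -6.84 (adjusted p = 1e-26), although Apoa2 alone of 27 passed (0 adjusted over the list alone). With hepatoma libraries 3 and 4 left out 27 of the 27 fell, and with libraries 1 and 2 left out 26. These pairs follow the level of hepatocyte transcripts itself, so the split narrows the spread within the group. The counts in these subsets, here and below, are therefore no separate support. Drug metabolism genes fell in 12 of 25 cases, among them Cyp3a2 and Ugt2b1 (57.4 ± 44.8 to 0.773 ± 0.569 RPKM), and Por rose (0 adjusted over the list alone, relative median -6.39, adjusted p = 4.1e-27), with 24 and 22 that fell in the same 2 subsets. Of the bile acid genes 9 of 14 fell, including Abcg5, the transporter Slco1a1 (-3.44 ± 0.57) and Hsd3b7 (-1.76 ± 0.37), with 13 adjusted over the list alone (relative median -5.53, adjusted p = 2.5e-20) and 14 in each subset. The rate-limiting enzyme Cyp7a1 went from 12.3 ± 7.49 to 0.991 ± 0.845 RPKM. Urea cycle and amino acid genes fell in 12 of 24 cases, among them Gls2 (-2.45 ± 0.29), Kmo (-3.72 ± 0.66) and Hal (-4.57 ± 0.81), with 18 adjusted over the list alone (relative median -5.38, adjusted p = 1.1e-28) and 24 and 22 in the subsets.

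Gluconeogenesis and glycogen genes fell in 5 of 12 cases (4 adjusted over the list alone, relative median -5.42, adjusted p = 1.6e-15, 12 and 9 in the subsets), led by Slc37a4 (-1.70 ± 0.26) and Ugp2 (-1.04 ± 0.23). Fatty acid oxidation genes fell in 7 of 14 cases, among them Acadvl (-1.74 ± 0.34), and Hadhb rose (7 lower adjusted over the list alone, relative median -3.66, adjusted p = 1.9e-15, 11 and 8 in the subsets). Beta-catenin and perivenous genes fell in 6 of 10 cases, among them Rnf43 (-0.77 ± 0.15) and Notum (-3.75 ± 0.82), with 6 adjusted over the list alone (relative median -4.33, adjusted p = 7e-14) and 9 and 7 in the subsets. Hepatocyte transcription factors fell in 3 of 10 cases, Nr1h3 (-1.82 ± 0.41), Rxra (-1.26 ± 0.36) and Nr1h4, with 1 adjusted over the list alone (relative median -3.21, adjusted p = 1.4e-10) and 9 and 5 in the subsets. Under median scaling 4 plasma protein, 20 drug metabolism, 13 bile acid, 19 amino acid, 8 gluconeogenesis, 11 fatty acid oxidation, 10 perivenous and 9 transcription factor genes were lower, and 0 genes of these lists were higher. Under quantile normalization 3, 13, 11, 13, 5, 10, 8 and 9 were lower and 0 higher.

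Cholesterol genes were split 7 higher and 7 lower of 15, with Mvd at 2.05 ± 0.31 and Nsdhl at -1.93 ± 0.32 on the log2 scale (7 and 8 adjusted over the list alone, relative median -2.18, adjusted p = 9.5e-07), and under both scalings 0 were higher and 8 lower. This list call was lost with all 3 rat groups in 1 fit (0.12). Growth hormone and IGF axis genes were split 5 and 5 of 11, with Igfbp3 (2.39 ± 0.30) higher and Igf1, Egfr, Igfals, Ghr and Socs2 lower (5 and 5 adjusted over the list alone, relative median -2.46, adjusted p = 5.6e-05), and under median scaling 0 were higher and 6 lower and the list call was lost (0.066). Mki67, Cdkn1a, Glul, Gpc3 and H19 were not listed, and Hnf4a and Igf2 were under the minimum for testing.

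**Figure D2:**
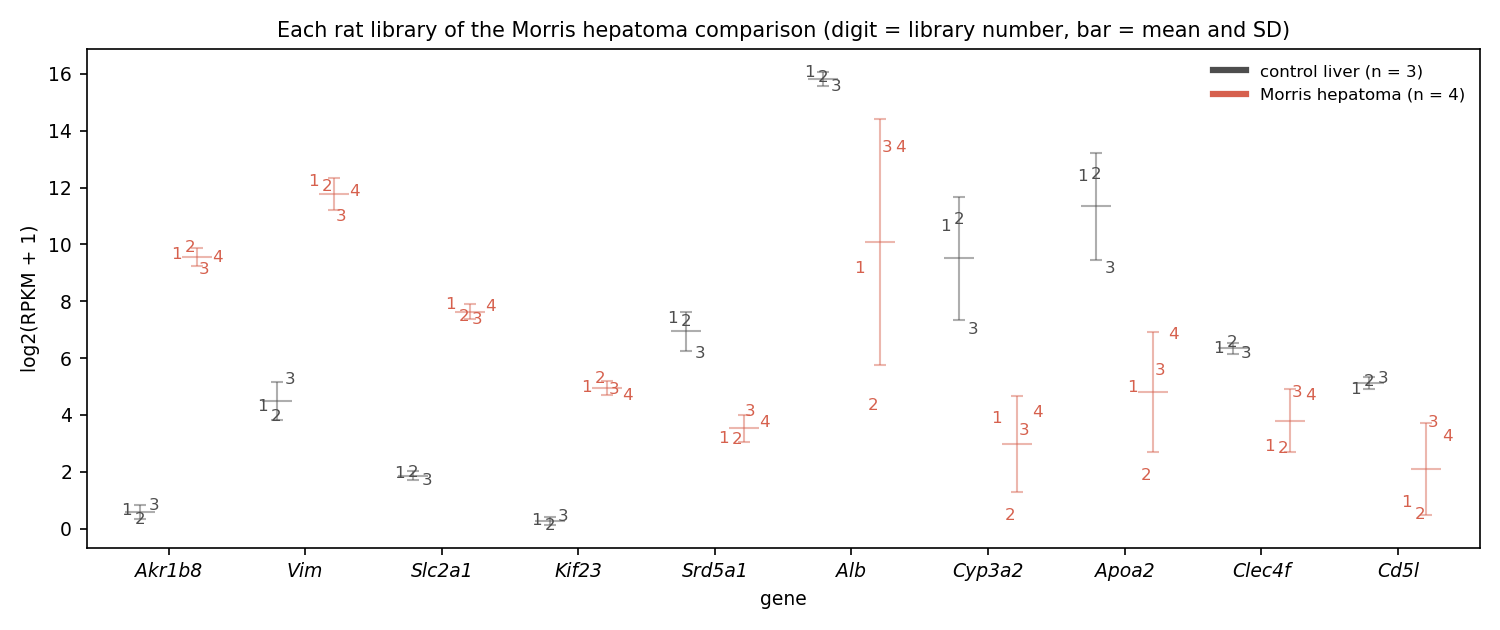
Expression of 10 genes in each library of the Morris hepatoma comparison, as log2(RPKM + 1), with grey digits for control liver (n = 3), red digits for hepatoma (n = 4), and bars for the mean and SD of each group. Akr1b8, Vim, Slc2a1 and Kif23 lay together in the 4 hepatoma libraries, while Alb ran from 19 to 10940 RPKM and Clec4f from 6.02 to 26.8 RPKM.

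Of the 97 genes that passed and are named by the rule, 18 lost the call without at least 1 library. Without control library 1 353 genes fell, without control library 2 346 and without control library 3 609, against 719 with all libraries. Without control library 1 or 2 the calls of Cyp3a2 (adjusted p up to 0.063), Ugt2b1 (0.066) and Notum (0.065) were lost. Apoa2 (up to 0.081), Cyp2c13 (0.13) and Cyp7a1 (0.071) lost theirs without either of these or hepatoma library 1, and Rup2, Pon1 and Cyp2c23 (0.15 each) also without control library 3. The call of Rxra (up to 0.11) was lost without control library 2 or 3 or hepatoma library 2.

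The third comparison asked which genes differed between liver 24 hours after partial hepatectomy and control liver. Regenerating liver held more transcripts of mitosis and DNA replication genes, and fewer of a small set that included Apoa4, an apolipoprotein, and G6pc, the glucose-6-phosphatase of gluconeogenesis. The microtubule regulator Stmn1 rose from 6.35 ± 1.58 to 80.9 ± 30.7 RPKM (GeneID 29332, log2 fold change 3.42 ± 0.29, adjusted p = 0.0033, n = 3 and 4). Thymidine kinase Tk1 rose from 5.10 ± 0.916 to 37.2 ± 10.6 RPKM (2.61 ± 0.22, adjusted p = 0.0022). The sterol transporter Abcg5 rose from 1.84 ± 0.0601 to 10.52 ± 1.05 RPKM (2.02 ± 0.12, adjusted p = 8.1e-05).

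Of 1703 genes tested, 361 rose, 13 fell and 1329 did not pass the threshold, and 174 of those that passed changed at least 2-fold. The median log2 fold change of the tested genes was 0.53. Setting library medians equal gave 19 higher and 59 lower, and quantile normalization 20 and 46. Here too the scalings rest on selected genes, most of them higher, and remove their shared rise by construction.

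The largest rises were in Rrm2, a subunit of ribonucleotide reductase (GeneID 362720, 3.74 ± 5.21 to 47.7 ± 26.9 RPKM), the securin Pttg1 (64193, 0.872 ± 0.611 to 23.1 ± 11.7), the mitotic kinase Cdk1 (54237, 1.59 ± 1.81 to 27.5 ± 12.8), its cyclins Ccnb2 (363088, 0.407 ± 0.0244 to 16.4 ± 8.35) and Ccnb1 (25203, 0.990 ± 1.13 to 22.2 ± 13.7), and Stmn1. The largest falls were in Apoa4 (25080, 1308 ± 136 to 206 ± 164 RPKM), G6pc (25634, 545 ± 267 to 127 ± 28.7), the ubiquitin ligase Rnf125 (361296, 26.7 ± 12.2 to 7.81 ± 1.62), the complement factor Cfd (54249, 18.2 ± 5.36 to 7.65 ± 1.75), Igfbp2 (25662, 18.97 ± 3.27 to 8.49 ± 2.79) and Slc25a47 (299316, 204 ± 29.4 to 102 ± 27.9). Their log2 fold changes ran from -2.92 ± 0.44 for Apoa4 to -1.03 ± 0.21 for Slc25a47.

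Of the mitosis genes 15 of 19 rose and 4 did not pass (19 adjusted over the list alone, relative median 2.08, adjusted p = 5e-05), among them Kif20a (2.74 ± 0.30) and Cdc20 (3.33 ± 0.43), with 4 under each scaling. Of the DNA replication and G1/S genes 15 of 20 rose (20 adjusted over the list alone, relative median 0.93, adjusted p = 0.00027), among them Tk1, Ccnd1 (9.99 ± 2.25 to 32.7 ± 4.94 RPKM) and the licensing factor Cdt1 (1.38 ± 0.18), with 1 under each scaling. These 2 calls were lost with an estimated correlation (adjusted p = 0.62 for each with an estimated correlation). Of the 6 listed plasma protein genes Apoa4 fell and 5 did not pass (1 adjusted over the list alone), and the list median lay 0.81 below that of the tested genes (adjusted p = 2.9e-10, 0.0064 with an estimated correlation and 0.06 under quantile normalization).

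Of the matrix genes Col1a1 (1.84 ± 0.32) and Vim (1.47 ± 0.28) rose and 6 of 8 did not pass (8 higher adjusted over the list alone, adjusted p = 0.44). The matrix list passed under median scaling (0.0071) and quantile normalization (0.013) and without control library 3 (0.047), while 0 of its members passed under either scaling. Of 5 cholesterol genes 1 rose (1 adjusted over the list alone, adjusted p = 0.77, and 0 under each scaling), and of 5 ribosome biogenesis genes 0 passed (4 higher adjusted over the list alone, adjusted p = 0.88). Of the 3 listed endothelial genes Emcn (1.54 ± 0.19) and Eng (1.19 ± 0.19) rose (3 adjusted over the list alone, and 0 under each scaling). Mki67, Cdkn1a, Myc, Alb, Hnf4a, Cyp7a1, Glul, Afp and H19 were not listed, and Gpc3 and Igf2 were under the minimum for testing.

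**Figure D3:**
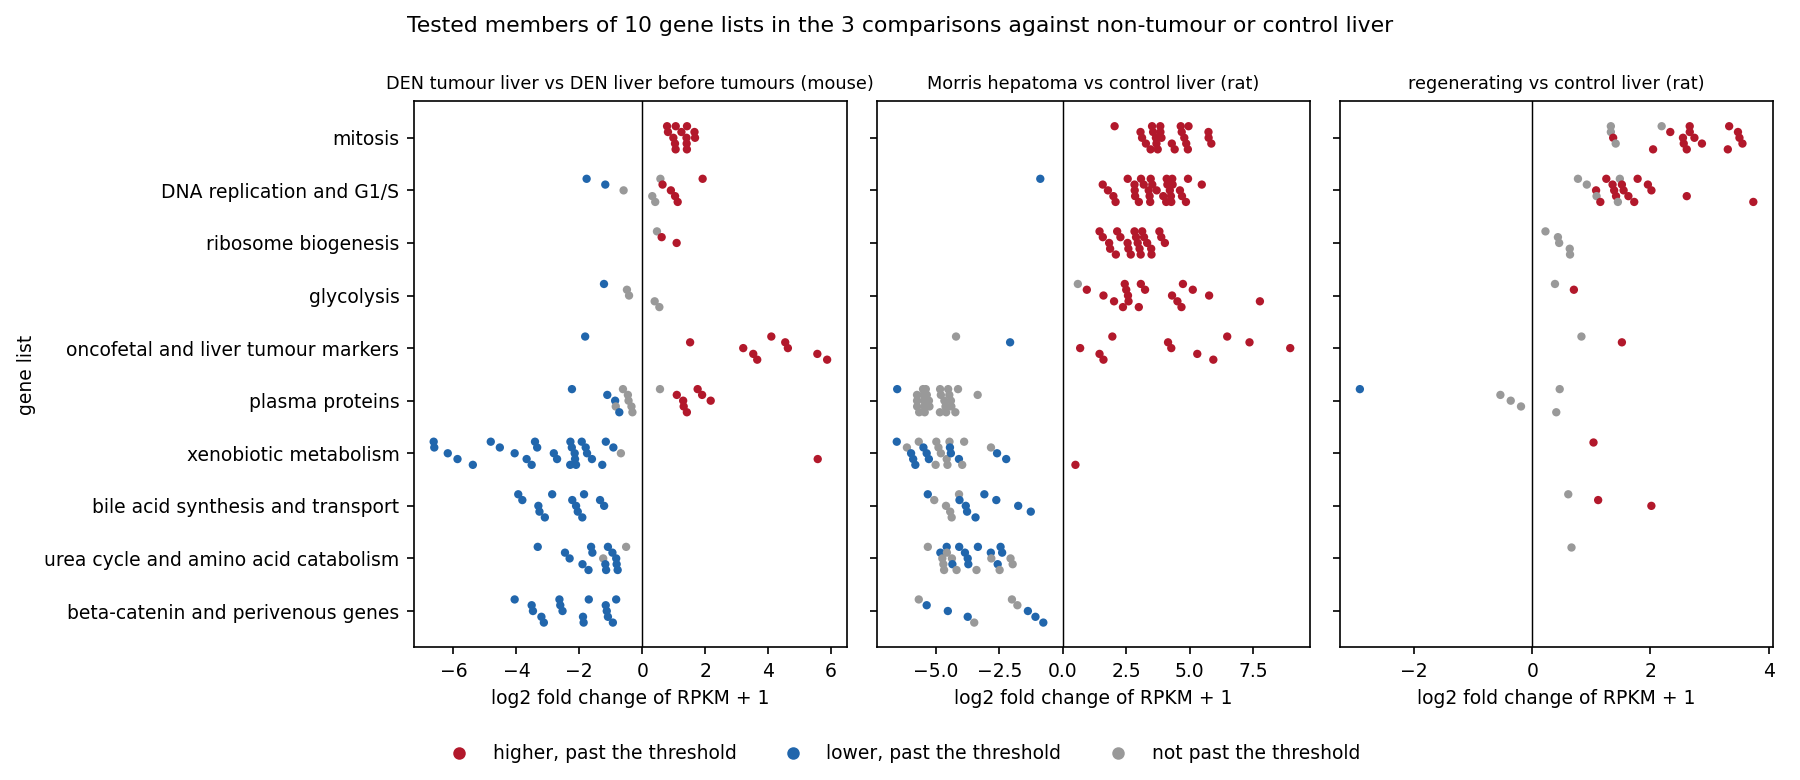
Log2 fold changes of RPKM + 1 of the tested members of 10 gene lists, 1 point per gene, in the comparisons of DEN liver with and before tumours (n = 3 each), Morris hepatoma and control liver (n = 4 and 3) and regenerating and control liver (n = 4 and 3), each on its own horizontal scale. All 13, all 24 and 15 of 19 mitosis genes rose in the 3 comparisons, and under median scaling 13, 23 and 4 of them.

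Without control library 1 20 genes rose and 1 fell, without control library 2 41 and 1, and without control library 3 338 and 15. Leaving out regenerating libraries 1 to 4 in turn gave 151 and 4, 78 and 2, 251 and 7, and 230 and 9. Of the 38 genes that passed and are named by the rule, 32 lost the call without at least 1 library (adjusted p up to 0.22), and Ccnb2, Stmn1, Tk1, Ccnd1, Abcg5 and Naprt1 kept it without any 1 library.

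Morris hepatoma and regenerating liver were then compared directly, on the 1752 genes listed in both rat tables, whose control values were identical in all 1752. All tested matrix, glycolysis and tumour marker genes were higher in hepatoma than in regenerating liver, as were 1352 of all 1673 tested genes. The matrix and tumour marker lists did not stand apart from the other genes in the main test, and glycolysis had too few genes for it. Lower in hepatoma were 67 genes, among them Srd5a1. Akr1b8 was at 759 ± 160 RPKM in hepatoma (n = 4) and 1.70 ± 0.576 in regenerating liver (n = 4), a log2 difference of 8.13 ± 0.20 (adjusted p = 1.5e-11). The steroid reductase Srd5a1 was at 11.04 ± 4.01 and 332 ± 16.1 RPKM (GeneID 24950, -4.85 ± 0.21, adjusted p = 1.9e-09).

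Of 1673 genes tested, 1352 were higher in hepatoma, 67 were lower and 254 did not pass the threshold, with a median difference of 1.47. Setting library medians equal gave 445 higher and 482 lower, and quantile normalization 495 and 433, with the same limit of scaling on selected genes. The other large rises were in the chromatin protein gene Hmga1 (GeneID 117062, 6.60 ± 0.20), Tspan8 (171048, 6.24 ± 0.34), the intermediate filament gene Vim (81818, 5.82 ± 0.25), S100a11 (445415, 5.78 ± 0.19) and the desaturase Scd (83792, 5.43 ± 0.39). The other large falls were in the carboxylesterase Ces2e (192257, -5.80 ± 0.31), the proline catabolism gene Prodh2 (361538, -4.55 ± 0.87), Ugt2a3 (289533, -4.12 ± 0.61), the carbonic anhydrase Car14 (791259, -3.98 ± 0.55) and Hdhd3 (688746, -3.52 ± 0.53).

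Of the mitosis genes 16 of 21 were higher in hepatoma than in regenerating liver (20 adjusted over the list alone), but the list did not stand apart from the other genes (relative median 0.33, adjusted p = 0.79), and under median scaling 1 was higher and 1 lower. DNA replication and G1/S genes were higher in 18 of 21 cases (20 adjusted over the list alone, adjusted p = 0.27), among them Cdt1 (2.74 ± 0.18) and Mcm7 (3.54 ± 0.23), with 10 higher and 1 lower under median scaling, where the list passed (0.032). Ccnd1 was higher by 2.07 ± 0.21. All 8 matrix genes (8 adjusted over the list alone, adjusted p = 0.27) were higher. So were all 5 tumour marker genes (5 adjusted over the list alone, adjusted p = 0.25) and all 5 ribosome biogenesis genes (5 adjusted over the list alone, adjusted p = 0.25). Under median scaling 3, 3 and 4 members of these lists were higher, and the ribosome biogenesis list passed (0.032). Under quantile normalization this list, the DNA replication list and the tumour marker list passed (0.036 each). The 3 listed glycolysis genes, Slc2a1 (5.38 ± 0.16), Hk1 (4.03 ± 0.18) and Pfkm (2.72 ± 0.21), were all higher (3 adjusted over the list alone, and 3 under each scaling). Of 6 plasma protein genes 0 passed (0 adjusted over the list alone), and the list median lay 5.90 below that of the tested genes (adjusted p = 3.1e-09, 0.26 with an estimated correlation, 0.077 under median scaling and 0.073 under quantile normalization). Without hepatoma library 1 or any 1 regenerating library the call of Prodh2 was lost (adjusted p up to 0.10).

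The title of the series sets tumours against regenerating tissue, so the calls of the comparisons were overlaid. Of 1486 genes tested in both rat comparisons, 291 were higher in both, and 292 would be higher in both if the lists were independent. Without control library 1 16 were higher in both against 17.8 for independent lists, without control library 2 29 against 30.5, and without control library 3 265 against 267. Ca1 and Rnf125 were lower in both, against 0.406 for independent lists. Cirbp, a cold-inducible RNA-binding protein gene, was higher in hepatoma and lower in regenerating liver, and 19 genes were lower in hepatoma and higher in regenerating liver. Of these 20 genes 3 kept the regenerating call without control library 1, 4 without control library 2 and 17 without control library 3. Under median scaling 2 of the 20 kept it, and under quantile normalization 3. The hepatoma call was kept in 11, 12 and 13 of them without control libraries 1, 2 and 3. Log2 fold changes correlated across the 1752 genes listed in both (Spearman 0.385, covariance 0.357), where genes are not independent replicates. Unchanged groups simulated against shared controls gave 206 genes listed in both (185 to 230 over 20 draws), a Spearman correlation of 0.94 and a covariance of 0.345 (0.214 to 0.531). The simulated spread of each gene was pooled over control and hepatoma libraries, and hepatocyte genes varied widely between the hepatoma libraries. The simulated covariance may therefore be too large, and it cannot tell how much of the observed one the shared controls give. The 3 controls are too few to give each rat group controls of its own, so part of any excess may come from the shared controls.

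**Figure D4:**
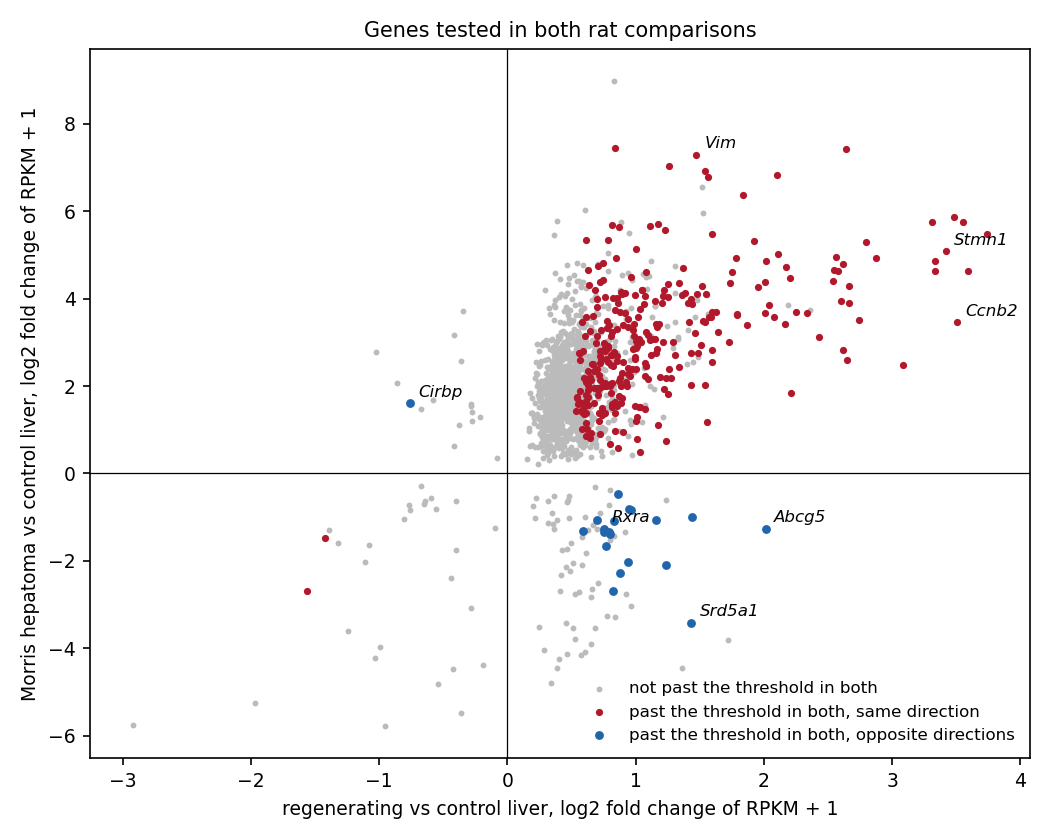
Log2 fold changes of RPKM + 1 against control liver for 1486 genes tested in both rat comparisons, regenerating liver (n = 4) on the horizontal axis and Morris hepatoma (n = 4) on the vertical axis, both against the same 3 control libraries. Red points (293) passed the threshold in both with the same direction and blue points (20) with opposite directions, among them Srd5a1 and Abcg5.

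Between the DEN model and the Morris hepatoma, 2103 genes of the same symbol were tested in both, of which 369 were higher in both against 302 for independent lists (two-sided Fisher exact test across genes, p = 7.8e-19) and 290 lower in both against 151 (p = 2.3e-61). A further 476 were lower in the DEN livers with tumours and higher in hepatoma, and 21 the other way round. Genes are not independent replicates and were preselected in each comparison, so the Fisher p-values here and below only describe these libraries. The number lower in both fell to 129 against 71.0 without control library 1, and to 131 against 72.6 without control library 2. Without control library 3 it was 237 against 126. Between the DEN model and regenerating liver, 513 were tested in both, with 63 higher in both against 34.7 (Fisher exact p = 5e-10), and Arl4d lower in both against 1.73 (Fisher exact p = 0.66). Without control library 1 4 genes were higher in both against 2.9 (Fisher exact p = 0.49), and without control library 2 8 against 3.7 (Fisher exact p = 0.013). The regenerating genes tested in both and called higher then numbered 11 and 14, against 133 with all libraries. Without control library 3 65 genes were higher in both against 31.2 (Fisher exact p = 1.6e-14), with 118 regenerating genes called higher. Apoa4 and Sesn2 were higher in the DEN livers with tumours and lower in regenerating liver, and 33 genes were lower and then higher.

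Of 445 genes tested in all 3 comparisons, 58 were higher in each, against 27.9 for independent lists, and 0 were lower in each. There were 4 genes higher in each without control library 1, against 2.51, and 8 without control library 2, against 3.24. Without control library 3 57 genes were higher in each, against 24.4. Of the 58 genes, those with the strongest evidence were Stmn1, Ccnb2, the secretory GTPase gene Rab3d, the tubulin Tuba1a, the phosphatase Cdkn3 and Nrm. In regenerating liver the calls of Rab3d and Tuba1a were lost without control library 1, and those of Cdkn3 and Nrm without control library 1 or 2 (adjusted p up to 0.069). Stmn1 rose by 1.97 ± 0.21 in the DEN model, 5.09 ± 0.33 in hepatoma and 3.42 ± 0.29 in regenerating liver, and Ccnb2 by 1.68 ± 0.18, 3.46 ± 0.21 and 3.51 ± 0.32. Another 9 genes were lower in both tumour models and higher in regenerating liver, namely Gdf2, Mgll, Adh4, Naprt1, Shmt1, Srd5a1, Abhd15, Plbd1 and Rxra. None (0 genes) had these 3 calls without control library 1 or 2, and 4 genes had them without control library 3. Srd5a1 changed by -3.42 ± 0.19, -3.41 ± 0.36 and 1.43 ± 0.27 in the 3 comparisons, Mgll, the monoglyceride lipase, by -1.88 ± 0.17, -0.82 ± 0.20 and 0.94 ± 0.16, and Naprt1 by -1.09 ± 0.16, -2.10 ± 0.58 and 1.24 ± 0.13. The difference between hepatoma and regenerating liver passed a direct limma test for Srd5a1, Mgll and Naprt1 (adjusted p = 1.9e-09, 3.6e-06 and 0.0079). Their choice by opposite calls made this nearly certain. The DEN model was not tested against the rat groups. In regenerating liver the call of Naprt1 held without any 1 library, but in hepatoma it was lost without any 1 control library or hepatoma library 2 (adjusted p up to 0.12). In regenerating liver the call of Srd5a1 (adjusted p up to 0.10) was lost without any of 6 of the 7 libraries and that of Mgll (up to 0.11) without control library 1 or 2 or regenerating library 1. Gdf2 and Adh4 lost the call without at least 1 library in each of the 3 comparisons (up to 0.13), Rxra in both rat comparisons (up to 0.22) and Shmt1 in regenerating liver (up to 0.11).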

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

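All tests of explanations in this part were chosen after the results were seen. Single libraries lay far from the others of their group, by Dixon's ratio above its critical value, in 5 of the named genes, and chance gives this in about 1 in 20 groups. They were Cdkn2a at 255 RPKM in hepatoma library 3, S100a6 at 1040 RPKM in hepatoma library 1, Apoa4 at 451 RPKM and G6pc at 84.3 RPKM in regenerating library 4, and Rab3d at 4.36 RPKM in regenerating library 1.

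In 20 genes hepatoma and regenerating liver moved in opposite directions from control, and the difference between them passed a direct limma test (adjusted p from 1.9e-09 to 0.0088). The genes were chosen for opposite calls against the same controls, so this outcome, also under the scalings, was nearly fixed and adds no support. The log2 difference of hepatoma from regenerating liver was -3.28 for Abcg5, -1.91 for Abhd15, -3.15 for Adh4, 2.36 for Cirbp, -1.80 for Fam213b, -2.97 for Gdf2, -3.52 for Hdhd3, -2.19 for Irx1, -1.77 for Mgll and -1.76 for Mpst. It was -3.34 for Naprt1, -2.43 for Plbd1, -2.22 for Rtn4rl2, -2.01 for Rxra, -1.91 for Serhl2, -2.09 for Shmt1, -4.85 for Srd5a1, -1.34 for St3gal3, -2.12 for Thpo and -2.43 for Usp2. The regenerating calls of these 20 genes mostly ended under alternatives, with 3 kept without control library 1, 4 without control library 2, 17 without control library 3, 2 under median scaling and 3 under quantile normalization. Their hepatoma calls were kept in 11, 12 and 13 genes without control libraries 1, 2 and 3, and in 19 under each scaling. The signs stayed opposite in 20 genes without any 1 control and in 18 under each scaling, and the difference between hepatoma and regenerating liver passed in 20 under each scaling.

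Hepatocyte transcripts differed between the hepatoma libraries, with 225 liver genes (at least 100 RPKM in control and under 5% of it in at least 1 hepatoma library) at a median of 1.24%, 0.105%, 20% and 14.3% of control in libraries 1 to 4. Against hepatocyte genes made by the hepatoma cells alone, the Kupffer cell genes Clec4f and Cd5l were higher in libraries 3 and 4 than in libraries 1 and 2, by at least 3.91 and 9.46 times. Host liver tissue in these pieces may be the source, since the medians of 50 tumour genes (at least 100 RPKM in hepatoma and under 2% of it in control) were 113%, 125%, 67.3% and 94.0% of their mean over the 4 libraries. The value of 94.0% in library 4 lay near 100%, and a mean over 4 libraries leaves some of them below it in any case. The labels give no dissection or cell content, and no biological explanation from the design was tested.

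Control library 3 stood apart from control libraries 1 and 2, with 179 of 225 liver genes lower, at a median of 38% of the others. The median excess of tumour genes in this library was 0.294% of their hepatoma level (quartiles 0.0285% and 0.769%, highest 2.58%), against a loss of 62%. These genes were chosen for lying under 2% of their hepatoma level in control, so a low excess was set in advance. Whether hepatoma RNA was in this library therefore stays open. Transcript length was argued against by a Spearman correlation of 0.11 across 7531 genes, with lengths of mouse transcripts of the same symbol. An inflammatory state of this liver may account for it, since 5 of 5 listed acute phase genes were higher than in both other controls, and the liver genes followed those of hepatoma libraries 3 and 4 (Spearman 0.87 and 0.90 across genes, against 0.14 and -0.09 for libraries 1 and 2). Handling of the tissue was not tested and stays open.

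More genes were lower than higher in the DEN livers with tumours, and more higher than lower in both rat comparisons. Among listed genes, a few abundant transcripts taking another share of the reads were argued against as the whole cause in DEN and Morris hepatoma. The 20 most abundant listed genes put a mean log2 factor of -0.28 on all others in DEN, against a median change of -0.56. The factor was 0.15 in Morris hepatoma against 1.58, and -0.01 in regenerating liver against 0.53. In the regenerating comparison these 20 genes held a share of 4.47% in control and 5.31% in regenerating libraries. Abundant genes such as Alb were not listed there, so the factor cannot decide the question for regenerating liver. The selection and scaling of the deposited values, RNA content per cell and, in the mice, age stay open and were not tested.

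Other splits of the same libraries into groups of these sizes say nothing about chance here, because the tables list only genes that differ in the real split. In the DEN model 10 splits are also too few for a share under 0.05, and 1 of them, the real one, reached 2481 genes, with 0 as the highest other. In each of the other comparisons 1 of 35 splits, the real one, reached 7761, 374 and 1419 genes, with 0 as the highest other.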

How the results depend on the processing

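The alternatives with the listed genes alone, the deposited p-values and pairs of hepatoma libraries left out were chosen after seeing the data, and the others were planned. Counts are given as higher and lower, the cause was not tested unless stated, and stricter thresholds and filters call fewer genes by construction. Scaling on the preselected genes removes their shared shift by construction. DEN (658 and 1823): filter at 5 gave 289 and 1072, median scaling 614 lower, quantile normalization 589 lower, deposited p-values 72 and 232, adjusted p under 0.01 344 and 781, a 2-fold minimum 326 and 729, and 1 library left out 409 to 631 and 922 to 1962. Morris hepatoma (7042 and 719): median scaling gave 2030 and 2389, quantile normalization 2514 and 1878, the replicate block 239 lower, all 3 rat groups 1551 and 63 (fewer genes tested), adjusted p under 0.01 320 lower, and 1 library left out 6720 to 6967 and 346 to 838. Regenerating liver (361 and 13): pseudocount 5 gave 237 and 8, no filter 22 lower, filter at 5 149 and 4, median scaling 19 and 59, quantile normalization 20 and 46, the replicate block 25 and 2, all 3 rat groups 229 and 3, deposited p-values 3 and 0, adjustment over the listed genes alone 1561 and 65, adjusted p under 0.01 21 and 0, a 2-fold minimum 165 higher, and 1 library left out 20 to 338 and 1 to 15. Hepatoma against regenerating liver (1352 and 67): median scaling gave 445 and 482, quantile normalization 495 and 433, hepatoma libraries 3 and 4 left out 103 lower, and 1 library left out 1305 to 1362 and 59 to 75.

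Overlaps of Morris hepatoma and regenerating liver (291 and 2) became 18 and 0 at adjusted p under 0.01, 133 higher at a 2-fold minimum, 1305 and 21 over the listed genes alone, and 16 to 265 and 0 to 5 without 1 control. DEN and Morris (369 and 290) became 169 and 68, 155 and 164 at a 2-fold minimum, and 363 to 369 and 129 to 237. DEN and regenerating liver (63 and 1) became 3 and 0, 23 at a 2-fold minimum, 167 and 12 over the listed genes alone, and 4 to 65 and 0 to 3.

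Reversed under median scaling and quantile normalization, which shift all genes, were, in Morris hepatoma, Acaca (-0.90, -0.92), Cd247 (-0.27, -0.12), Fcrla (-0.93, -0.74), Ifih1 (-0.80, -0.80) and Bcl6 (-0.23, -0.24). Against regenerating liver these were Mvd (-0.46, -0.44), Eng (-0.52, -0.36), Socs3 (-0.16, -0.08), Cbr3 (-0.46, -0.18) and, under median scaling alone, Cdc25c (-0.20). Of 279 named results 50 lost the call and 10 reversed under median scaling, 54 and 9 under quantile normalization, 65 lost it with the replicate block, 16 with pseudocount 0.1, 5 with pseudocount 5 and 0 without a filter. Of 240 tested with filter at 5 12 lost it, and of 114 with all 3 rat groups 14. With 1 library left out 262 of 1898 tests lost the call and 1 gained it. Of the list tests 32 lost the call with an estimated correlation and 28 kept their side of the threshold, while median scaling ended 5 list calls and added 9, and quantile normalization 5 and 7. Count-table alternatives were not run, and for DEN a fit of all groups equals the one reported. Relative depth alone is known in rats, so what depth limits was not tested.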

Other observations

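In the DEN livers with tumours other metabolic genes were mostly lower. Of 9 gluconeogenesis and glycogen genes 7 fell (9 adjusted over the list alone, camera adjusted p = 0.11, and 0.032 under median scaling), among them Khk (-2.04 ± 0.30), with 3 under median scaling and 1 under quantile normalization. Of 12 fatty acid oxidation genes 8 fell and Fgf21 rose by 2.73 ± 0.30 (10 and 2 adjusted over the list alone, adjusted p = 0.55), and under median scaling 1 was lower and 2 higher. Of 9 lipogenesis genes 7 fell, led by Thrsp (423 ± 56.7 to 35.6 ± 5.08 RPKM), and Fads2 rose (8 and 1 adjusted over the list alone, adjusted p = 0.11, and 0.026 under median scaling). Of 5 glycolysis genes Eno1 alone passed, at -1.22 ± 0.16 (1 adjusted over the list alone, adjusted p = 0.63), and 2 were higher under median scaling and 3 under quantile normalization. Of 5 hypoxia genes 4 fell (4 adjusted over the list alone, adjusted p = 0.52), and under median scaling 1 was lower and 1 higher. Both tested cholesterol genes, Sqle (1.25 ± 0.25) and Lss (1.18 ± 0.25), rose. The call of Sqle was lost without any library before tumours or library 1 with tumours (adjusted p up to 0.069), and that of Lss without any of these or library 3 with tumours (up to 0.096). Of 7 growth hormone and IGF axis genes 5 fell, among them Ghr (-2.12 ± 0.31), and Igfbp1 rose from 26.6 ± 12.8 to 598 ± 132 RPKM (5 and 2 adjusted over the list alone, adjusted p = 0.91), with 2 higher under each scaling and 3 and 2 lower. Of 5 NRF2 targets Srxn1 rose by 1.93 ± 0.31 while Ephx1 and Gstm3 fell (1 and 2 adjusted over the list alone, adjusted p = 0.91), with 1 and 0 lower under the 2 scalings. Nop58 and Nop56 rose among 3 ribosome biogenesis genes, and Stat2 fell among 3 interferon genes, with 0 lower under each scaling. The calls of Nop56 (adjusted p up to 0.12), Gstm3 (up to 0.15) and Stat2 (up to 0.10) were lost without any of 5, 5 and 4 of the 6 libraries. Those left out without loss were library 2 with tumours for Nop56, library 1 with tumours for Gstm3 and library 3 of either group for Stat2.

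Cell type genes were listed in small numbers for the DEN model. The cholangiocyte genes Krt23 (0.671 ± 0.346 to 11.1 ± 0.697 RPKM) and Sox9 (1.26 ± 0.20) rose. The erythroid genes Alas2 (73.9 ± 6.07 to 9.65 ± 4.64 RPKM), Klf1 and Tfrc fell, with 1 lower under median scaling and 2 under quantile normalization. Of 5 macrophage and Kupffer cell genes Lyz2 (0.83 ± 0.18) and Cd68 rose and Timd4 (-0.96 ± 0.22) and Clec4f (-1.97 ± 0.49) fell (2 and 3 adjusted over the list alone), with 2 higher and 0 lower under each scaling. Their median was -0.96 while camera gave the direction up (adjusted p = 0.55). The calls of Timd4, Clec4f, Klf1 and Tfrc were lost without any library before tumours or library 3 with tumours (adjusted p up to 0.098, 0.16, 0.083 and 0.098), and that of Lyz2 without library 2 before tumours or library 3 with tumours (up to 0.078). Of the T and NK cell genes and B cell genes 0 were tested, and of the neutrophil genes S100a8 was tested and did not pass.

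In Morris hepatoma all 9 endothelial genes rose (9 adjusted over the list alone, adjusted p = 0.39), led by Flt1 (3.35 ± 0.25), with 3 under median scaling. Of 7 macrophage and Kupffer cell genes 5 rose, among them Itgam (3.42 ± 0.25) and Lyz2 (5.07 ± 0.50), and Clec4f fell (5 and 2 adjusted over the list alone, adjusted p = 0.24), with 2 and 2 under median scaling. Of 5 T and NK cell genes 4 rose and Gzma fell (4 and 1 adjusted over the list alone, adjusted p = 0.45), and under both scalings 0 were higher. Fcrla rose among 2 B cell genes, Spp1 (6.84 ± 0.20) rose among 2 cholangiocyte genes, and Ifih1 rose as the 1 interferon gene. Under both scalings the changes of Fcrla and Ifih1 turned negative, and without control library 1 the call of Fcrla was lost (adjusted p = 0.051). All 8 p53 targets rose (8 adjusted over the list alone, adjusted p = 0.30), with 2 under median scaling. Of 14 NRF2 targets 12 rose, among them Srxn1 (2.34 ± 0.18) and Txnrd1 (2.98 ± 0.26), and Gsta4 fell (12 and 2 adjusted over the list alone, adjusted p = 0.64), with 4 higher and 2 lower under median scaling and 6 and 1 under quantile normalization. Of 6 lipogenesis genes Scd (6.03 ± 0.45), Elovl6 and Acaca rose and Thrsp fell (3 and 1 adjusted over the list alone, adjusted p = 0.086), with 1 higher and 3 lower under both scalings. Of 5 acute phase genes Socs3 rose and 4 did not pass (4 lower with hepatoma libraries 3 and 4 left out and 3 with libraries 1 and 2 left out), with a relative median of -6.40 (1 adjusted over the list alone, adjusted p = 0.00022). This list call was lost with an estimated correlation (0.22), under median scaling (0.36) and under quantile normalization (0.27). No neutrophil or erythroid gene was listed.

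Few genes of the other lists were tested in regenerating liver. Por (1.03 ± 0.14), Abcg8, Mcm2, Hk1 and Rxra rose, and Sesn2 fell, as members of the drug metabolism, bile acid, tumour marker, glycolysis, transcription factor and p53 lists. Mcm2 was also counted in the DNA replication list. Under each scaling 0 of the drug metabolism, tumour marker, glycolysis and transcription factor genes passed. Of the urea cycle, fatty acid oxidation, lipogenesis, acute phase, interferon, NRF2 and immediate early genes 0 passed, and of the perivenous and hypoxia genes 0 were tested. No gene of macrophages, T and NK cells, B cells, neutrophils, cholangiocytes or erythroid cells was listed. Against regenerating liver, hepatoma had more Dusp6 (4.44 ± 0.24), Adm (4.74 ± 0.31), Psrc1 and Cdh5 and less Nags (-3.49 ± 0.61), Acads, Nr1h3 and Abcg8. Of 5 cholesterol genes 2, among them Mvd, were higher and 1 was lower (2 and 1 adjusted over the list alone, adjusted p = 0.059), with 0 higher and 3 lower under both scalings. This list passed in 7 alternatives (0.033 to 0.047). The call of Nags was lost without any 1 regenerating library (adjusted p up to 0.072), and that of Mvd (up to 0.13) without any 1 library other than hepatoma library 3 and regenerating library 4.

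A further test, chosen after the result was seen, concerned male-biased liver genes, since Mup and Cyp2d9 transcripts fell in the DEN livers with tumours. Of 29 male-biased genes 27 were listed, and 24 fell and 0 rose. Of 28 female-biased genes 7 were listed, of which Cyp2a4, Abcd2, Cyp2c40 and Rtn4 rose and Sult1e1 fell. Without the Mup genes, the genes named by the rule and all members of the 30 lists, 12 of 13 male-biased genes fell and 0 rose, and 3 of 6 female-biased genes rose and 1 fell. The 2 directions differed between these shorter lists (two-sided Fisher exact p = 0.0071 across genes, which are not independent), with 4 female-biased genes behind it. Loss of the male pattern of liver gene expression in tumour tissue may be a candidate explanation, while age and reads shared among Mup copies stay open.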
